A study of Homo sapiens with 12 samples.

How the data were processed

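RNA from 3 lymphoma cell lines was sequenced in 12 libraries: 6 of KARPAS-422 (3 DMSO, 3 CPI-169), 4 of Pfeiffer (2 DMSO, 2 GSK343) and 2 of RL (DMSO). Per the labels' protocols, compound or vehicle was added when the cells were seeded, and the cells were pelleted 4 days later and lysed in Trizol or in RLT buffer. Which library had which lysis is not stated. The compound of the treated KARPAS-422 cells is written as CPI-169 in the protocol, the name used here. The lines also differ in the number series of their libraries, so that line and library series cannot be told apart.

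The authors deposited 1 table of FPKM values, which are fragment numbers divided by transcript length and by the mapped fragments of the library, for 63129 Ensembl gene IDs. Reads were aligned to hg19 with TopHat 1.4.1 and quantified with Cufflinks, per the submitters' processing notes; the Cufflinks version, the gene annotation release, the handling of strand and the library kit are not given in the sources used here. FPKM corrects for length and total fragments, and an abundant transcript in 1 library lowers the values of all others there. The 10 most abundant genes held 6.35% to 8.52% of the FPKM sum in Pfeiffer libraries and 1.93% to 2.43% in the others. The FPKM sums ran from 371965 to 630387. Read counts were not used here, so the absolute depth is unknown and no counting interval is given. From the steps between the lowest values, the depth relative to the lowest-numbered DMSO library of each line was 0.646 to 1 in KARPAS-422, 1 to 1.34 in Pfeiffer and 0.774 to 1 in RL. A value of exactly 0 can be a failed estimate, and such genes are said to be listed at 0; all 13 mitochondrially encoded genes are listed at 0 in every library. Antisense and overlapping genes are uncertain because the counting of strands is not given.

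Columns were matched to samples by their titles, and groups and replicate numbers were taken from the labels. Symbols and hg19 loci came from the FPKM table, with positions 1-based. The separate annotation table has 30 symbols that differ, having been turned into dates, and was not used. Missing values left out 77 genes. The 5756 IDs on patches and alternative haplotypes had 0 genes above 0 FPKM. Gene classes came from GENCODE 29 by Ensembl ID, which matched 18047 of the tested genes; no coordinates were taken from it.

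Genes with at least 1 FPKM in at least 2 of the 12 libraries were kept, which left 18731 genes, 12026 of them protein-coding. Values were transformed to log2(FPKM + 1), and every log2 fold change is on that scale, which understates changes of genes with low values. The 5 groups were fitted together with limma 3.58.1 in R 4.3.3 (intensity trend, 7 residual and 3.45 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 5 groups share 1 estimate of the spread per gene, so a gene that differs between the 2 GSK343 libraries has a larger standard error in every comparison. Contrasts were CPI-169 against DMSO in KARPAS-422, GSK343 against DMSO in Pfeiffer, the difference of these, and RL against each line and against their mean. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. No camera call on the lists set beforehand held with an estimated correlation, in any contrast. That correlation was estimated once per list from all 12 libraries, so a split between the 2 GSK343 libraries can raise it in every comparison. For interferon-stimulated and cholesterol biosynthesis genes it was 0.56 and 0.843. With Pfeiffer fitted alone it was 0.602 and 0.896. With KARPAS-422 fitted alone it was 0.223 and 0.258, and neither list passed there (camera adjusted p = 0.42 for both). Overlaps used Fisher's exact test, and the treated lines share no control libraries.

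The groups, tests, 24 gene lists, alternatives and the rule for named genes were set before the data were examined. Of the lists, 22 had members to test; the interferon genes and the mitochondrially encoded genes had none. The rule took EZH2 and 15 other genes in every contrast; the 8 highest and 8 lowest fold changes per treatment among called genes whose treated libraries all lay on the same side of the DMSO libraries, with a mean of at least 2 FPKM in the higher group; the 3 list members with the smallest adjusted p per list with a call or at least 3 changed members; the 8 highest and 8 lowest in both lines; the 6 highest and 6 lowest in RL; and the 5 genes with the smallest adjusted p for the difference between lines. TXNIP and VPREB3 were picked from these for the difference between lines after their values were seen. Some genes that the rule took are not reported here.

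The fit was tested on simulated data for 18731 genes. For the KARPAS-422 comparison it called 61.2%, 88.1% and 98.5% of genes changed by 1.5, 2 and 4-fold and 9 of 206 genes called were unchanged ones. For the Pfeiffer comparison it called 41.8%, 82.1% and 97.0%, with 4 of 151 calls being unchanged genes. Every simulated group had the same spread per gene. These shares therefore do not cover the wider spread found between the 2 GSK343 libraries. In simulated sets, 1 of 100 unchanged sets had a camera p under 0.05. The simulated genes varied independently, whereas estimated correlations in the tested lists reached 0.843, for cholesterol biosynthesis genes. That rate therefore does not carry over to lists of correlated genes. Alternatives were pseudocounts of 0.1 and 0.5, no filter or a minimum of 5 FPKM, quantile normalization, median scaling, protein-coding genes only, no intensity trend, a 2-fold minimum, each line or the DMSO libraries fitted alone, the replicate number as a block, and each of the 12 libraries left out. Leaving out 1 library of a group of 2 leaves a lone library, whose spread is then taken from the other groups. Calls from such fits do not measure the spread within that group. Figures were drawn with matplotlib 3.10.9.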

Results

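RNA sequencing was carried out on 12 libraries from 3 human lymphoma cell lines. KARPAS-422, Pfeiffer and RL are established lines of germinal centre B cell-like diffuse large B cell lymphoma, and each carries a gain-of-function change in EZH2. EZH2 is the catalytic subunit of the histone methyltransferase complex PRC2, and the change lies in its SET domain. Per the labels, KARPAS-422 and Pfeiffer respond phenotypically to EZH2 inhibition and RL does not. KARPAS-422 cells received CPI-169 (n = 3) or DMSO (n = 3), Pfeiffer cells received GSK343 (n = 2) or DMSO (n = 2), and RL cells received DMSO (n = 2). CPI-169 and GSK343 are EZH2 inhibitors, both used at 1.5 µM, and the vehicle was 0.1% DMSO. All cells were harvested after 4 days. The series concerns EZH2 and the interferon-stimulated gene response, and the comparisons ask which transcripts changed with inhibition in the responsive lines and how RL differed from them at baseline.

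Between 14018 and 16391 genes reached 1 FPKM per library. Replicates of KARPAS-422 DMSO correlated at Pearson's r of 0.9939 to 0.9969 across the tested genes, those of CPI-169 at 0.993 to 0.9958, Pfeiffer DMSO at 0.9961 and RL DMSO at 0.9972. The 2 GSK343 libraries stood further apart, at r = 0.97 and a root mean square log2 difference of 0.497, against 0.185 between the Pfeiffer DMSO libraries. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

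In KARPAS-422, interferon-stimulated genes rose with CPI-169. IFIT1, which binds viral RNA, went from 2.75 ± 0.688 to 84.0 ± 12 FPKM (SD, n = 3 each; log2 fold change 4.51, SE 0.545, limma with Benjamini-Hochberg adjustment, adjusted p = 4.91e-05). XAF1 rose from 6.55 ± 1.04 to 149 ± 3.57 FPKM, IFIT3 from 4.93 ± 0.503 to 72.5 ± 4.34 and the antiviral GTPase gene MX2 from 17.8 ± 0.459 to 122 ± 8.46. IFI27 (log2 fold change 3.36), IFI35 (3.03), IFI44L (2.50), the RNase L activator gene OAS1 (2.36), MX1 (1.56) and PARP12 (1.49) also rose. Of the 64 interferon-stimulated genes tested, 57 were higher, 0 lower and 7 did not pass, with a median log2 fold change of 1.51. The count was 60 higher and 0 lower adjusted over the list alone, and camera gave an adjusted p of 1.41e-16 (adjusted p = 0.402 with an estimated correlation). The list medians of the 3 CPI-169 libraries against the DMSO mean were 1.54, 1.49 and 1.56. ISG15, which encodes a ubiquitin-like protein, averaged 306 ± 53.2 FPKM with DMSO and 788 ± 84.8 with CPI-169. It missed the threshold (log2 difference 1.37, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0575), the spread being pooled over all lines. With KARPAS-422 fitted alone its adjusted p was 0.00136, and over the alternatives it ran from 5.83e-05 without GSK343 replicate 1 of Pfeiffer (5.98e-05 without replicate 2) to 0.158. MX1 passed at an adjusted p of 0.0213 but not without DMSO replicates 1 or 3 or CPI-169 replicates 1 or 3 (0.0516 to 0.0538 with limma and Benjamini-Hochberg adjustment; 3.54e-06 to 0.0745 over all alternatives).

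**Figure D1:**
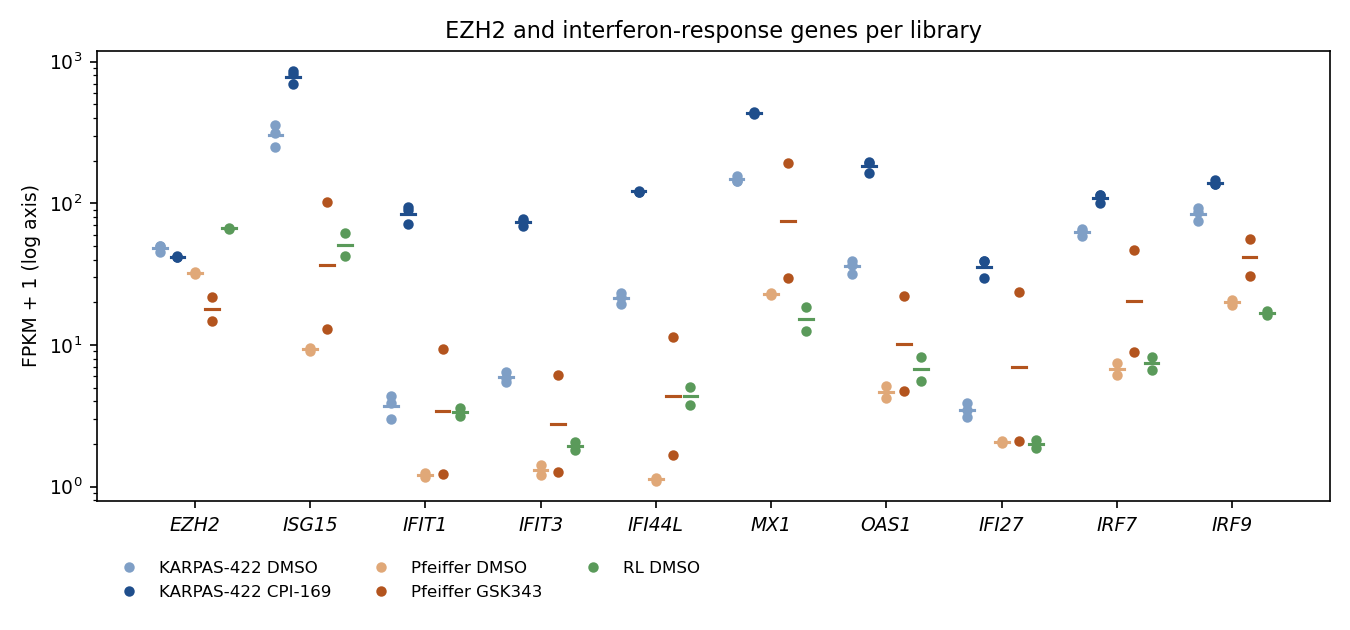
FPKM + 1 of EZH2 and 9 interferon-response genes in each library, on a log axis; points are libraries and bars are group means of log values. The CPI-169 libraries lie above the KARPAS-422 DMSO libraries for all 9 interferon-response genes, and the 2 GSK343 libraries lie apart for most of them, as for IFIT1 at 8.42 and 0.223 FPKM.

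Some genes upstream of that response and in antigen presentation moved as well, in a comparison where 54.2% of all tested genes were called. STAT2 rose from 32.4 ± 1.80 to 123 ± 4.02 FPKM (log2 fold change 1.89) and IRF9, its DNA-binding partner, from 83.8 ± 8.51 to 139 ± 6.26 (0.73), while IRF3 fell by 0.96 on the log2 scale. IRF7 differed by 0.80 and did not pass (adjusted p = 0.154, limma with Benjamini-Hochberg adjustment), the spread being pooled over all lines. With KARPAS-422 fitted alone it passed (adjusted p = 3.93e-04, limma), and over the alternatives its adjusted p reached 0.33 with limma. Of 22 interferon receptor and JAK-STAT-IRF genes, 12 were higher and 6 lower, also adjusted over the list alone, with a camera adjusted p of 0.269 (adjusted p = 0.416 with an estimated correlation). Nucleic acid sensors and adaptors had 9 of 16 members higher and 4 lower, equal adjusted over the list alone. The adaptor gene MYD88 (1.73) and UNC93B1, a trafficking chaperone gene of endosomal Toll-like receptors (2.17), rose and MB21D1, which encodes cGAS, fell by 1.15 on the log2 scale. Camera gave that list an adjusted p of 0.0317 (adjusted p = 0.402 with an estimated correlation). MHC class I genes had 15 of 19 members higher and 1 lower (16 and 1 adjusted over the list alone). The proteasome activator gene PSME1, HLA-F and the peptide transporter gene TAP2 rose, and the list had a median of 0.67 and a camera adjusted p of 5.47e-04 (adjusted p = 0.402 with an estimated correlation). HLA genes are highly polymorphic and similar in sequence, so their values are uncertain. The 11 interferon-gamma-associated genes had 6 members higher and 3 lower, also adjusted over the list alone, and MHC class II genes had 7 of 15 higher and 6 lower, the same adjusted over the list alone. Camera passed neither list (adjusted p of 0.154 and 0.689; adjusted p = 0.416 and 0.824 with an estimated correlation), and the MHC class II list had a median of -0.17 but a mean of 0.13. No interferon gene could be tested: 21 of the 24 listed were found and their highest value in any library was 0.508 FPKM.

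Cholesterol biosynthesis genes rose with CPI-169. INSIG1, a sterol-regulated retention factor of the endoplasmic reticulum, went from 17.1 ± 0.220 to 101 ± 4.62 FPKM. Of 22 genes, 20 were higher and 0 lower, also adjusted over the list alone, with a median of 1.03 and a camera adjusted p of 2.55e-05 (adjusted p = 0.537 with an estimated correlation). Germinal centre B cell genes had 14 of 20 members higher and 2 lower, also adjusted over the list alone, with a camera adjusted p of 0.0034 (adjusted p = 0.402 with an estimated correlation). BACH2, a transcriptional repressor of B cells, rose from 0.830 ± 0.222 to 25.95 ± 2.72 FPKM and SERPINA9 from 24.9 ± 1.89 to 108 ± 3.27, and HTR3A fell by 1.39 on the log2 scale. BCL6 was 202 ± 7.38 FPKM with DMSO and 220 ± 6.79 with CPI-169 and did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.762). Plasma cell genes had 10 of 20 members higher and 0 lower (9 and 0 adjusted over the list alone), with a camera adjusted p of 0.0229 (adjusted p = 0.465 with an estimated correlation). Among them the immunoglobulin joining chain gene IGJ rose from 1.82 ± 0.542 to 34.4 ± 3.87 FPKM, whereas PRDM1, the regulator of plasma cell differentiation, was at 0.0720 ± 0.02 and 0.319 ± 0.0869 and did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.2). Without GSK343 replicates 1 and 2 of Pfeiffer the adjusted p of PRDM1 was 0.00328 and 0.00347, in a range of 0.00241 to 0.54 over the alternatives. Cell cycle genes had 25 of 44 members lower and 9 higher (27 and 10 adjusted over the list alone), with a median of -0.42 and a camera adjusted p of 0.0229 (adjusted p = 0.646 with an estimated correlation). That call was lost with quantile normalization (median -0.33, camera adjusted p = 0.232), with a minimum of 5 FPKM (0.083) and with protein-coding genes alone (0.0737), in a range from 3.51e-04 to 0.232. The mitotic genes KIF11 and TPX2 fell by 0.90 and 0.80 on the log2 scale, and the replication licensing gene CDT1 rose by 1.36.

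EZH2 mRNA was 47.4 ± 2.61 FPKM with DMSO and 41.0 ± 0.540 with CPI-169 (log2 difference -0.20, SE 0.117, limma with Benjamini-Hochberg adjustment, adjusted p = 0.175). The difference passed with KARPAS-422 fitted alone (adjusted p = 0.0133, limma), after median scaling (0.0415) and without GSK343 replicates 1 or 2 of Pfeiffer (0.00527 and 0.00526), in a range of 0.00526 to 0.446. MYC rose from 102 ± 7.18 to 198 ± 5.95 FPKM. The highest fold changes chosen by the naming rule were those of TNNI1, the slow skeletal troponin I gene (1:201373625-201398994; 9.92 ± 1.90 to 271 ± 37.8 FPKM), IFIT1, L3MBTL4 (log2 fold change 4.48), XAF1, S100A4 (4.31), RGCC (4.17), PRR15L (4.16) and FAM184A (3.95). The lowest were those of LTA, encoding lymphotoxin alpha (6:31539831-31542101; 252 ± 11.7 to 22.95 ± 0.888 FPKM), KLF10, OGN, BHLHE41, PPAP2B, ZNF90, DHRS2 and the immediate early gene EGR1, which fell by 2.52 to 3.40 on the log2 scale. CDKN2A fell by 0.65 on the log2 scale, CDKN2C rose by 1.02 and CDKN1A did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.26). CDKN2A no longer passed with KARPAS-422 fitted alone (adjusted p = 0.0586, limma). Its call was also lost without DMSO replicates 2 or 3 or CPI-169 replicate 2 (adjusted p of 0.0581, 0.0583 and 0.0579 with limma). Over the alternatives its adjusted p ran from 8.66e-04 to 0.0586 with limma. CDKN1A, with a log2 difference of 0.62, passed with KARPAS-422 fitted alone, where the spread is not pooled over all lines. Over the alternatives its adjusted p reached 0.46 with limma.

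Of 18731 genes tested in KARPAS-422, 5047 were higher and 5106 lower with CPI-169, and 1176 and 591 of these by at least 2-fold. Quantile normalization gave 4712 and 5577, and median scaling 4504 and 5890. Replication-dependent histone genes, whose transcripts lack a poly(A) tail and which were singled out after their values were seen, had medians of 0.257, 0.296 and 0.176 FPKM in the DMSO libraries and 1.25, 0.615 and 0.684 in the CPI-169 libraries. Among the remaining lists, members higher and lower numbered 2 and 6 of 13 for PRC2 components and demethylases, 4 and 2 of 13 for developmental Polycomb targets (SOX9 rose by 1.73, MSX1 fell by 1.54 on the log2 scale), 7 and 5 of 17 for memory and activation genes, and 6 and 7 of 20 for B cell identity genes. They numbered 5 and 10 of 25 for apoptosis regulators, 6 and 4 of 21 for MYC and ribosome biogenesis genes, 7 and 5 of 19 for NF-kappaB targets, and 4 and 8 of 19 for heat shock and stress genes. All these counts were equal when adjusted over the list alone. Cyclin-dependent kinase inhibitors had 1 of 6 higher and 3 lower (1 and 4 adjusted over the list alone). Markers of other cell types, listed as a check, had 6 higher and 2 lower of 11 for T and NK cells, where NCAM1 rose from 0.0104 ± 0.0120 to 2.18 ± 0.259 FPKM and LCK fell from 11.2 ± 0.631 to 4.24 ± 0.406. They had 2 and 0 of 3 for myeloid cells and 1 and 1 of 8 for epithelial and stromal cells, also adjusted over the list alone. Camera passed none of these lists, the lowest adjusted p being 0.089 for heat shock and stress genes (adjusted p = 0.402 with an estimated correlation). Without the filter on low values that list passed (median -0.35, camera adjusted p = 0.0081, in a range up to 0.235).

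In Pfeiffer, every cell cycle gene tested fell with GSK343, and interferon-stimulated genes rose, more so in replicate 1 than in replicate 2. CDC45, a component of the replicative helicase, went from 31.1 ± 0.542 FPKM (SD, n = 2) to 4.34 and 4.95 in the 2 GSK343 libraries (log2 fold change -2.51, SE 0.113, limma with Benjamini-Hochberg adjustment, adjusted p = 6.96e-07). The checkpoint kinase gene CHEK1 fell from 53.9 ± 1.87 to 11.9 and 5.35 FPKM, GINS2 from 55.6 ± 1.60 to 10.7 and 5.29, and the transcription factor gene E2F1 from 17.3 ± 0.249 to 4.61 and 3.98. All 44 cell cycle genes were lower, also adjusted over the list alone, with a median of -1.87 and a camera adjusted p of 1.43e-33 (adjusted p = 0.108 with an estimated correlation). The list medians of the 2 libraries were -1.60 and -2.19.

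Of 64 interferon-stimulated genes, 30 were higher and 1 lower with GSK343 (34 and 1 adjusted over the list alone), with a median of 0.83 and a camera adjusted p of 3.92e-14 (adjusted p = 0.355 with an estimated correlation). Genes that rose with similar values in both libraries included PARP12, from 3.36 ± 0.115 to 9.29 and 9.47 FPKM, IFI35, from 10.98 ± 1.84 to 36.1 and 27.2, and RNF213, from 28.9 ± 1.11 to 65.0 and 53.5. Others differed between the libraries: IFI44L was 0.124 ± 0.0370 FPKM with DMSO and 10.3 and 0.658 with GSK343, and ISG15 was 8.31 ± 0.368 with DMSO and 101 and 12.1 with GSK343. ISG15 missed the threshold (log2 difference 1.97, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0501), as did IFIT1, IFIT3, MX1, OAS1 and IFI27, while IRF9 (1.05), IRF7 (1.58), IFI44 (2.04) and IFI44L (1.95) passed. Over the alternatives the adjusted p of ISG15 reached 0.317 with limma. Without replicate 2, the differences were 3.46 for ISG15, 2.97 for IFIT1, 2.22 for IFIT3, 3.08 for MX1, 2.27 for OAS1 and 3.52 for IFI27. Without replicate 1 these genes differed by -0.05 to 0.49. The calls of IRF7 and IFI44 were lost when any of the 12 libraries other than GSK343 replicate 2 was left out, with adjusted p of 0.0629 to 0.182 and 0.0548 to 0.161 (limma with Benjamini-Hochberg adjustment). That of IFI44L was lost without any of the DMSO, CPI-169 or RL libraries (0.0501 to 0.136), so these calls lie at the edge of the threshold. The median of the list was 1.24 in replicate 1, where 61 members lay above both DMSO libraries, and 0.29 in replicate 2, where 40 lay above and 11 below; chance places 33.3% above. RN7SL2, a structured RNA singled out after its values were seen, was 4318 and 1151 FPKM in these libraries, against 3179 and 3152 with DMSO. Without replicate 1, 26 of the 64 genes were higher and 1 lower, and without replicate 2, 58 were higher and 1 lower, the lone library being assumed to vary like the other groups. Without DMSO replicates 1 and 2 of Pfeiffer, 19 and 20 were higher.

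The lists next to that response had small medians. Of 22 interferon receptor and JAK-STAT-IRF genes 9 were higher and 1 lower (11 and 1 adjusted over the list alone), with a camera adjusted p of 0.00428 (adjusted p = 0.108 with an estimated correlation). STAT2 went from 26.1 ± 0.319 to 44.0 and 38.7 FPKM, and SOCS1, a feedback inhibitor of the pathway, from 1.39 ± 0.247 to 3.99 and 2.80. MHC class I genes had 7 of 19 members higher and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0178, adjusted p = 0.444 with an estimated correlation), among them HLA-E, HLA-G and HLA-C. MHC class II genes had 6 of 15 higher and 0 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.00833, adjusted p = 0.355 with an estimated correlation), among them HLA-DOB, HLA-DMA and HLA-DOA. Memory and activation genes had 8 of 17 higher and 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.00816, adjusted p = 0.287 with an estimated correlation). The adhesion receptor gene CD44 rose from 347 ± 36.3 to 724 and 821 FPKM and the chemokine receptor gene CCR7 from 13.4 ± 1.24 to 130 and 37.9. NF-kappaB targets had 7 of 19 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00816, adjusted p = 0.108 with an estimated correlation), with CFLAR, TNFAIP3 and CD70 higher. Without GSK343 replicate 1 the calls of MHC class I (camera adjusted p = 0.278), MHC class II (0.133), memory and activation genes (0.099) and NF-kappaB targets (0.099) were lost, and without DMSO replicate 1 that of MHC class I (0.0766). Over the alternatives these p ran from 5.14e-04 to 0.278, 7.87e-04 to 0.133, 0.00251 to 0.099 and 1.26e-04 to 0.099. Cholesterol biosynthesis genes had 0 of 22 higher and 7 lower (0 and 12 adjusted over the list alone; camera adjusted p = 0.00428, adjusted p = 0.578 with an estimated correlation), and HMGCS1 went from 126 ± 7.72 to 79.8 and 40.9 FPKM. The cholesterol list fell mainly in replicate 2, with medians of -0.17 and -1.09 in the 2 libraries, and without replicate 2 it had 5 members higher and 5 lower and no call (camera adjusted p = 0.764, in a range of 8.81e-13 to 0.764).

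EZH2 mRNA fell with GSK343, from 31.2 ± 0.555 to 13.8 and 20.9 FPKM (log2 fold change -0.84, SE 0.143, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00169), and JARID2, a PRC2 cofactor, rose by 0.82. PRDM1 rose from 1.30 ± 0.199 to 12.4 and 6.05 FPKM. The highest fold changes chosen by the naming rule were those of TYMP (2.42), TP53INP1 (8:95938200-95961639; 0.831 ± 0.144 to 8.31 and 8.32 FPKM), CCR7, IGFBP4 (2.08), PRDM1, IFI44 (2.04), CHST2 (2.04) and EEF1A2 (2.02). The lowest were those of MND1 (4:154265801-154336270; 34.6 ± 4.79 to 3.53 and 2.88 FPKM), PBK, PNMAL1, GINS2, C12orf75, CHEK1, WDR76 and CDC45. TXNIP rose from 5.13 ± 0.563 to 31.5 and 26.2 FPKM. BCL6, at 107 ± 2.56 FPKM with DMSO, was 92.3 and 268 in the 2 GSK343 libraries, and CDKN1A, at 10.0 ± 0.0767, was 21.1 and 3.18; neither passed. Without replicate 1, BCL6 differed by 1.31 and CDKN1A by -1.40, and without replicate 2 CDKN1A differed by 1.01. These fits leave 1 GSK343 library and hold no spread between GSK343 libraries, so no call is drawn from them. Over the alternatives the adjusted p of BCL6 and CDKN1A reached 0.57 and 0.955 with limma.

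Of 18731 genes, 2254 were higher and 3281 lower with GSK343, and 340 and 492 of these by at least 2-fold. Quantile normalization gave 2652 and 2548, moving the share of higher genes among those called from 40.7% to 51%. Without DMSO replicates 1 and 2 of Pfeiffer, 1207 and 1444 genes were higher and 1796 and 2093 lower, and without GSK343 replicate 1, 4458 were higher and 4223 lower. Members higher and lower were 5 and 2 of 16 for nucleic acid sensors, 5 and 1 of 11 for interferon-gamma-associated genes, 3 and 2 of 13 for developmental Polycomb targets, 5 and 5 of 20 for germinal centre genes, 5 and 1 of 20 for B cell identity genes and 6 and 4 of 25 for apoptosis regulators. They were 0 and 5 of 19 for heat shock and stress genes, 0 and 1 of 11 for T and NK cell markers and 0 and 1 of 3 for myeloid markers; these counts were equal adjusted over the list alone. The counts were 1 and 6 of 13 (3 and 6 adjusted over the list alone) for PRC2 components, 5 and 5 of 20 (6 and 5) for plasma cell genes, 0 and 1 of 6 (1 and 2) for cyclin-dependent kinase inhibitors, 0 and 7 of 21 (0 and 9) for MYC and ribosome biogenesis genes, and 3 and 1 of 8 (4 and 1) for epithelial and stromal markers, where EPCAM fell from 135 ± 0.309 to 49.8 and 66.7 FPKM. Camera passed none of these, the lowest adjusted p being 0.0543 for interferon-gamma-associated genes and for MYC and ribosome biogenesis genes (adjusted p = 0.287 and 0.488 with an estimated correlation). Without GSK343 replicate 2, camera passed nucleic acid sensors (adjusted p = 0.00806), developmental Polycomb targets (0.00526), plasma cell genes (0.0324), B cell identity genes (0.0237) and MYC and ribosome biogenesis genes (0.00557). Over the alternatives these p reached 0.943, 0.767, 0.962, 0.254 and 0.555. B cell identity genes also passed without DMSO replicate 2 (0.0375), MYC and ribosome biogenesis genes without DMSO replicate 1 (0.0389) and CPI-169 replicate 2 (0.0485), and interferon-gamma-associated genes without DMSO replicate 1 (0.0389) and CPI-169 replicates 1, 2 and 3 (0.0477, 0.047 and 0.0484). Interferon-gamma-associated genes passed as well with the replicate block (0.0436), with Pfeiffer fitted alone (0.0373), with pseudocounts of 0.1 and 0.5 (0.0433 and 0.0478) and without the filter on low values (9.21e-04), in a range up to 0.127. The last 3 settings also passed MYC and ribosome biogenesis genes (0.0409, 0.0478 and 0.00171). B cell identity genes passed with a pseudocount of 0.1 (0.0433), and heat shock and stress genes (0.00848) and epithelial and stromal markers (0.0266) without the filter. Fitted alone, the 4 Pfeiffer libraries gave 0 higher and 0 lower genes with limma, where 4634 had an unadjusted p under 0.05, so the calls rest on the spread shared with the other lines.

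**Figure D2:**
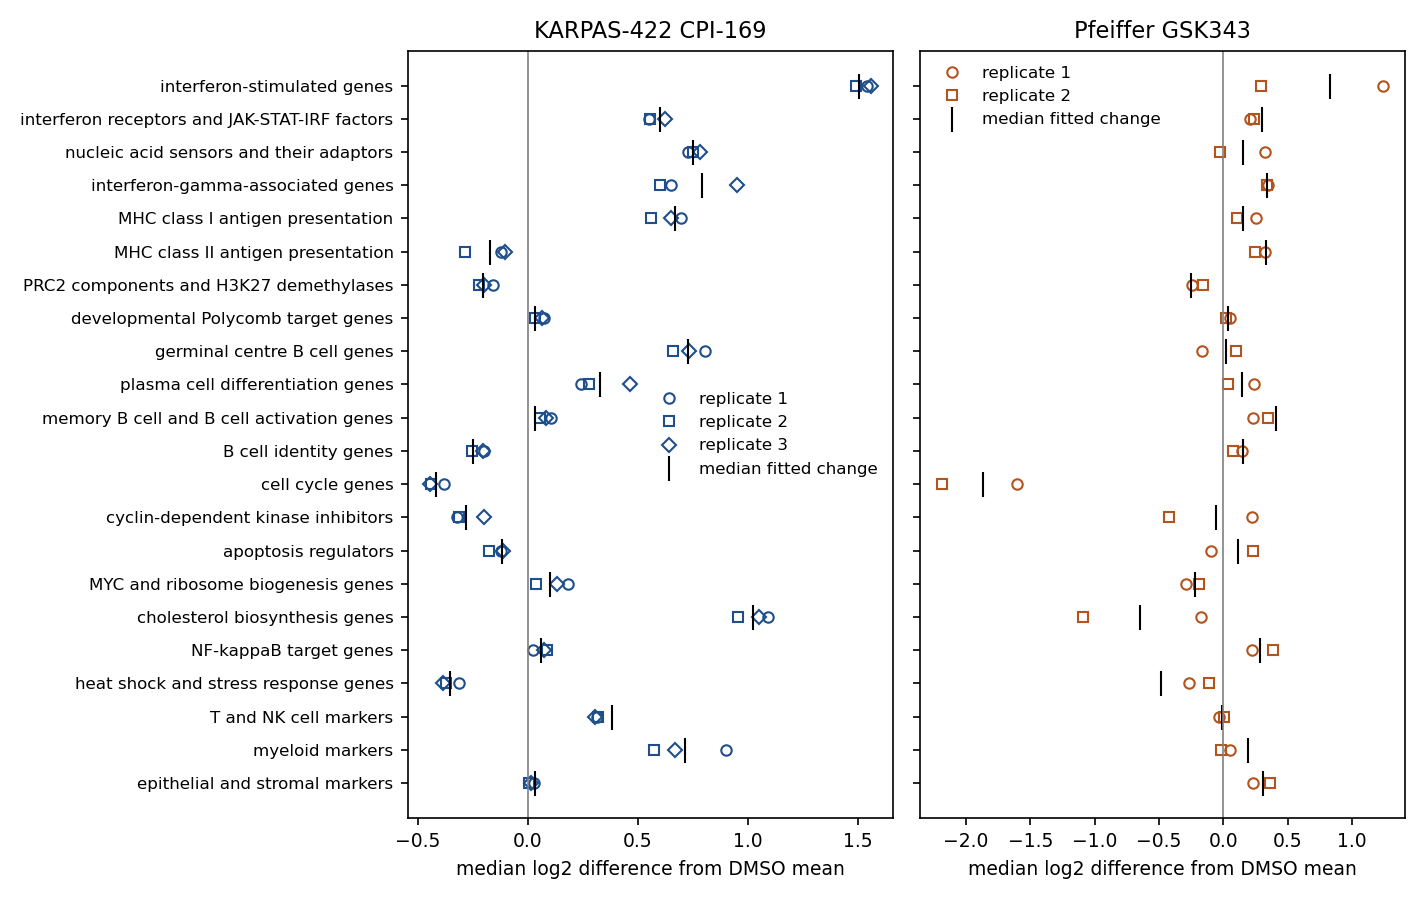
Median log2 difference from the DMSO mean of the same line for each of the 22 tested lists, per treated library (open symbols), with the median fitted log2 fold change as a black line. Interferon-stimulated genes lie at 1.49 to 1.56 in the CPI-169 libraries and at 1.24 and 0.29 in the GSK343 libraries.

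Both treated lines shared more calls than independent lists would. IFI44, TRIB1, LSP1, IFI44L, TP53INP1, ABAT, FCRL3 and ATHL1 were the highest in both by the naming rule; LSP1, encoding a leukocyte actin-binding protein, rose by 2.50 with CPI-169 and 1.97 with GSK343. MTFR2, CKS1B, RP11-192N10.2, CDCA8, FAM72D, C1orf112 and ESCO2 were the lowest in both; CDCA8, a subunit of the chromosomal passenger complex, fell by 1.33 and by 1.35 on the log2 scale. CKS1B is listed at 2 loci that could share reads, and FAM72D has near-identical paralogs, so their values are uncertain. Higher in both were 1059 genes against 607 for independent lists (ratio 1.74, Fisher's exact test, one-sided p = 1.47e-105). Lower in both were 1315 against 894 (ratio 1.47, Fisher's exact test, one-sided p = 1.21e-69). Another 909 were called with opposite signs, for which the number under independent lists was not worked out. Both contrasts use the same estimate of the spread per gene, so their calls are not independent, and genes are not independent replicates. Fold changes correlated across genes at Pearson's r = 0.24 and Spearman's rho = 0.232. Taken from single pairs of a treated and a DMSO library of the same number, they correlated at r = 0.0955 to 0.278 between lines and at 0.58 between the 2 Pfeiffer pairs. Genes higher with CPI-169 had a median of 0.07 in Pfeiffer (camera p = 7.96e-06; p = 0.0966 with an estimated correlation), and those lower had -0.11 (camera p = 1.12e-04; p = 0.108 with an estimated correlation). Genes higher with GSK343 had a median of 0.23 in KARPAS-422 (camera p = 1.13e-08; p = 0.109 with an estimated correlation), and those lower had -0.13 (camera p = 1.26e-04; p = 0.318 with an estimated correlation). The shared counts moved by over 1.5 times when a Pfeiffer library was left out: higher in both were 590 and 682 without DMSO replicates 1 and 2 and 2027 without GSK343 replicate 1, and lower in both were 748 and 841 without the DMSO replicates.

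**Figure D3:**
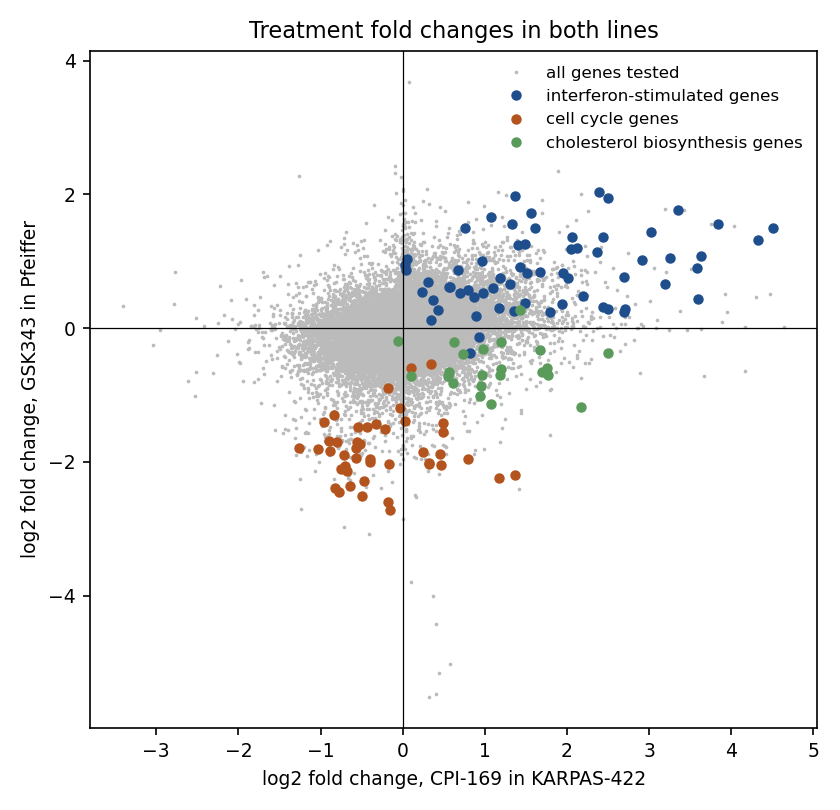
Log2 fold change with GSK343 in Pfeiffer against that with CPI-169 in KARPAS-422 for 18731 genes, with 3 lists in colour. Cell cycle genes lie at a median of -1.87 on the Pfeiffer axis, and cholesterol biosynthesis genes at 1.03 on the KARPAS-422 axis and -0.65 on the Pfeiffer axis.

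The fold changes themselves differed between the treated lines for cholesterol and cell cycle genes. Cholesterol biosynthesis genes had 21 of 22 members with a higher fold change in KARPAS-422 and 0 with a lower one, also adjusted over the list alone, with a median difference of 1.73 (camera adjusted p = 3.08e-07; adjusted p = 0.551 with an estimated correlation). Cell cycle genes had 43 of 44 higher and 0 lower (44 and 0 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 3.5e-17; adjusted p = 0.456 with an estimated correlation). Interferon-stimulated genes had 29 of 64 higher and 4 lower, also adjusted over the list alone, with a median of 0.70 (camera adjusted p = 9.03e-04; adjusted p = 0.695 with an estimated correlation). Without GSK343 replicate 2 the median for interferon-stimulated genes was 0.10 and the call was lost (camera adjusted p = 0.443, in a range of 7.66e-13 to 0.443). Other lists passed without 1 library: germinal centre genes without GSK343 replicate 2 (0.00745) and KARPAS-422 DMSO replicate 1 (0.0459), and nucleic acid sensors (0.0136) and apoptosis regulators (0.0187) without GSK343 replicate 1. Germinal centre genes also passed with quantile normalization (0.0419), median scaling (0.0421) and no filter on low values (0.00723), and nucleic acid sensors with quantile normalization (0.0419), a minimum of 5 FPKM (0.0474) and no filter (0.0305). MHC class I (0.0358) and MYC and ribosome biogenesis genes (0.0305) passed with no filter. Over the alternatives these p reached 0.27, 0.157, 0.443 and 0.348, and that of apoptosis regulators 0.324. TXNIP fell by 1.26 on the log2 scale in KARPAS-422 and rose by 2.28 in Pfeiffer, and the B cell gene VPREB3 rose by 0.81 and fell by 1.11. In all, 4460 genes had a higher and 3523 a lower fold change in KARPAS-422. The lines also differ in compound, in library series and in the number of libraries, which this contrast cannot separate.

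At baseline, RL differed from both responsive lines in transcripts near 0 on one side and abundant on the other. THY1, a cell surface glycoprotein gene, was 137 ± 3.94 FPKM in RL (SD, n = 2) against 0.0476 ± 0.0527 in KARPAS-422 (n = 3) and 0.0393 ± 0.0429 in Pfeiffer (n = 2), with a log2 difference of 7.05 from the mean of both (limma with Benjamini-Hochberg adjustment, adjusted p = 8.55e-13). LSAMP was 105 ± 1.71 FPKM in RL and listed at 0 in the DMSO libraries of the other lines, and CD48, ADA, ASB2 and the ectoenzyme gene CD38 were higher in RL by 5.18 to 5.80. GTSF1 was 0.0812 ± 0.0366 FPKM in RL against 74.9 ± 13.6 and 128 ± 12.4, and MRFAP1L1, NETO2, OAT and ANXA5 were lower by 5.16 to 5.72 on the log2 scale, as was ACN9, listed at 0 in RL. EZH2 was higher in RL (65.7 FPKM; log2 difference 0.76) and MYC was 174 FPKM there (0.98).

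Interferon-stimulated genes were lower in RL than in KARPAS-422, where 48 of 64 were lower and 4 higher, also adjusted over the list alone, with a median of -1.71 (camera adjusted p = 6.48e-07; adjusted p = 0.487 with an estimated correlation). Against Pfeiffer, 14 were lower and 22 higher (14 and 21 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.614; adjusted p = 0.911 with an estimated correlation), and without RL replicate 1 the higher count was 14. Without either GSK343 replicate, which adds to the shared spread, 7 were higher in RL than in KARPAS-422. MX1 was 14.5 FPKM in RL, 146 ± 6.60 in KARPAS-422 and 21.9 ± 0.325 in Pfeiffer, against which it did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.399, in a range of 0.00436 to 0.751). Against the mean of both lines, 39 interferon-stimulated genes were lower and 7 higher, also adjusted over the list alone (median -0.78, camera adjusted p = 0.00864; adjusted p = 0.75 with an estimated correlation). MHC class I genes were lower in 16 of 19 and higher in 0 (camera adjusted p = 2.88e-04; adjusted p = 0.337 with an estimated correlation). MHC class II genes were lower in 14 of 15 and higher in 1 (median -1.49, camera adjusted p = 3.95e-04; adjusted p = 0.337 with an estimated correlation). Developmental Polycomb targets, of which 13 of 56 listed genes passed the filter, were lower in 12 and higher in 1 (median -1.16, over the alternatives -2.11 to -0.10; camera adjusted p = 0.00823; adjusted p = 0.337 with an estimated correlation). All these counts were equal adjusted over the list alone.

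Germinal centre genes were higher in RL in 17 of 20 and lower in 1 (18 and 2 adjusted over the list alone; median 1.24, camera adjusted p = 1.66e-05; adjusted p = 0.152 with an estimated correlation). BCL6 was 278 FPKM in RL against 202 ± 7.38 in KARPAS-422 and 107 ± 2.56 in Pfeiffer. It passed against Pfeiffer and not against KARPAS-422 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.226), where it was called only without GSK343 replicates 1 or 2 (1.22e-04 and 1.06e-04) and in the DMSO libraries alone (8.54e-04; 0.0159 with the replicate block). Cell cycle genes were higher in 41 of 44 and lower in 1 (median 0.94, camera adjusted p = 2.53e-10; adjusted p = 0.337 with an estimated correlation). Cholesterol biosynthesis genes were higher in 16 of 22 and lower in 0 (camera adjusted p = 3.95e-04; adjusted p = 0.55 with an estimated correlation). MYC and ribosome biogenesis genes were higher in 14 of 21 and lower in 3 (camera adjusted p = 0.0151; adjusted p = 0.426 with an estimated correlation), a call lost with protein-coding genes alone (0.0707). These 3 counts were equal adjusted over the list alone. The other 14 lists did not pass against the mean of both lines. Without GSK343 replicates 1 and 2, B cell identity genes, cyclin-dependent kinase inhibitors and epithelial and stromal markers passed, each at a camera adjusted p of 0.0482 and 0.0478. Without the filter on low values, PRC2 components (0.017), B cell identity genes (0.0429) and cyclin-dependent kinase inhibitors (0.0418) passed, the last also with a minimum of 5 FPKM (0.0461). Over the alternatives the p of these 4 lists reached 0.344 for B cell identity genes, 0.163 for the inhibitors, 0.319 for epithelial and stromal markers and 0.238 for PRC2 components.

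Several of these differences from the mean passed against only 1 of the lines. Cholesterol biosynthesis genes were higher than in KARPAS-422 in 20 of 22 and lower in 0 (median 1.64, camera adjusted p = 2.4e-05), and against Pfeiffer 6 were higher and 1 lower (0.22, camera adjusted p = 0.449). MYC and ribosome biogenesis genes were higher than in KARPAS-422 in 15 of 21 and lower in 1 (camera adjusted p = 0.00117), and against Pfeiffer 7 were higher and 8 lower (camera adjusted p = 0.83). MHC class II genes were lower than in Pfeiffer in 13 of 15 and higher in 2 (median -2.43, camera adjusted p = 6.79e-04). Against KARPAS-422, 8 of them were lower and 4 higher (-0.53, camera adjusted p = 0.366), which passed only with quantile normalization (0.0369). Developmental Polycomb targets were lower than in Pfeiffer in 10 of 13 and higher in 1 (median -1.35, camera adjusted p = 0.039), a call lost with a minimum of 5 FPKM (0.342) and with quantile normalization (0.0507). The median ran from -3.12 to -0.13 over the alternatives. Against KARPAS-422, 6 of them were lower and 2 higher (-0.28, in a range of -2.67 to 0; camera adjusted p = 0.25). Plasma cell genes differed in opposite directions: 12 of 20 were higher and 1 lower than in KARPAS-422 (median 1.12, camera adjusted p = 0.0051), and 4 were higher and 13 lower than in Pfeiffer (-1.09, camera adjusted p = 0.039). B cell identity genes passed against Pfeiffer, with 12 of 20 higher and 4 lower (median 1.27, camera adjusted p = 0.0127), and not against KARPAS-422 (camera adjusted p = 0.435). These counts were equal adjusted over the list alone, except for 8 higher MYC and ribosome biogenesis genes against Pfeiffer. MHC class I, germinal centre and cell cycle genes passed against each line, in the direction found against the mean. Cyclin-dependent kinase inhibitors missed the threshold against Pfeiffer (camera adjusted p = 0.0549). They passed in some settings, as in the DMSO libraries alone (0.0338), in a range of 0.0176 to 0.0852. NF-kappaB targets missed it against KARPAS-422 (camera adjusted p = 0.0588). They passed in some settings, as with protein-coding genes alone (0.011), in a range of 0.00716 to 0.0691. With an estimated correlation none of the calls against a single line held (lowest adjusted p = 0.237).

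Of 18731 genes, 5970 were higher and 7606 lower in RL than in the mean of both lines, where the median over all genes was -0.11. That excess of lower genes depended on the processing. With a minimum of 5 FPKM 4804 were higher and 4869 lower than in the mean, and with quantile normalization 6541 and 6600. Without the filter on low values 6840 were higher and 9230 lower. Against KARPAS-422, 6302 were higher and 6214 lower, and against Pfeiffer, 6661 were higher and 7252 lower. Quantile normalization moved the median over all genes against Pfeiffer from -0.03 to 0.13 and turned the balance of calls, to 7838 higher and 6224 lower. With median scaling 7097 were higher and 6996 lower than in Pfeiffer, with a minimum of 5 FPKM 5310 and 4743, and with protein-coding genes alone 4852 and 4005. Against KARPAS-422 median scaling gave 6788 higher and 5899 lower, and protein-coding genes alone gave 4115 and 4698. Each line is a single line, so these tests compare libraries of 3 lines and not responsive with non-responsive lymphomas.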

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

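Of the tests in this part, those of a wrong label and of RNA from KARPAS-422 cells were chosen after the result was seen. Treatment effects differed between KARPAS-422 with CPI-169 and Pfeiffer with GSK343, by limma's test of the difference itself: 4460 genes had a higher and 3523 a lower fold change in KARPAS-422. The median difference of log2 fold changes was 1.73 for cholesterol biosynthesis genes, 1.39 for cell cycle genes and 0.70 for interferon-stimulated genes, the last falling to 0.10 without GSK343 replicate 2 (camera adjusted p = 0.443, in a range of 7.66e-13 to 0.443). Among the genes fixed beforehand, IFIT1 differed by 3.01, IFIT3 by 2.55, MYC by 0.81, EZH2 by 0.64 and PRDM1 by -1.79. Without GSK343 replicates 1 and 2 these were 4.48 and 1.54, 3.69 and 1.41, 0.49 and 1.13, 0.36 and 0.92, and -1.32 and -2.25. PRDM1 lay below 1 FPKM in KARPAS-422 with and without CPI-169, where log2(FPKM + 1) understates a change. With a pseudocount of 0.1 its log2 fold change there was 1.27, so the size of -1.79 depends on that scale. The call of IFIT1 was lost with pseudocounts of 0.1 and 0.5, without the filter and without DMSO replicate 1 of Pfeiffer (adjusted p up to 0.188 with limma). That of IFIT3 was lost with a pseudocount of 0.1 (0.173), and that of EZH2 with the replicate block (0.0517) and without that DMSO library (0.0614). Differences that did not pass in the main fit had opposite signs without replicates 1 and 2 for ISG15 (0.88 and -2.09), MX1 (1.19 and -1.51), IFI44L (1.94 and -0.83), CDKN1A (2.02 and -0.38) and BCL6 (-1.19 and 0.34). These fits leave 1 GSK343 library, so no call is drawn from them. The protein-coding genes with the smallest adjusted p for the difference were PRR15L (4.14), PNMAL1 (2.86), KIAA1210 (2.84), RGCC (4.81) and SLC25A43 (2.85). Of 141 other named genes, 114 differed, 72 with a higher fold change in KARPAS-422 and 42 with a lower one. Many of these were named for large changes in 1 treated line, so this share is not evidence on the lines; over all tested genes 42.6% differed. Compound, line and library series differ together, so none of these differences can be assigned to the compound or to the line.

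The interferon-stimulated genes rose further in GSK343 replicate 1 than in replicate 2 of Pfeiffer, with list medians of 1.24 and 0.29 against DMSO. An untreated library like the DMSO libraries, with a wrong label, is argued against for replicate 2. Its cell cycle list lay at a median of -2.186, with all 44 members below both DMSO libraries. An untreated library was taken to lie above -0.5, a cut set after the result was seen. The value shows that replicate 2 differs from the DMSO libraries. It cannot tell treatment from another cause of a fall in cell cycle genes. A scaling difference between the libraries is argued against by quantile normalization, after which the lists still differed by a median of 1.103 (0.916 without it). RNA of treated KARPAS-422 cells in replicate 1 would have to reach a ratio of 0.123 to explain the rise, and the median ratio over 56 genes of those cells that the other Pfeiffer libraries lack was 0.00165. The libraries also differed in structured RNA: RN7SL2 was 4318 FPKM in replicate 1 and 1151 in replicate 2, against 3179 and 3152 with DMSO, and histone genes had medians of 2.45 and 1.35 FPKM, against 3.16 and 2.72. What stays open, untested, is a difference in preparation or RNA composition, or in the cultures, such as the effective exposure or the state of the cells, which may also bear on the cholesterol list, at -0.17 and -1.09 in the same libraries.

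The count of 10153 genes called in KARPAS-422 was set against the other splits of the 6 libraries into 3 and 3. As many were called in 1 of the 10 splits, the real one, and at most 2 genes in the others; 10 splits are too few for a share under 0.05.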

How the results depend on the processing

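The alternative without the chromosome 1 stretch and the per-library values were chosen after seeing the data. Outside the settings below, counts stayed within 1.5 times their value. Requiring 5 FPKM gave 4869 genes lower in RL than in the mean of the other lines (4804 higher) and 4743 lower than in Pfeiffer (5310 higher). Protein-coding genes alone gave 4565 lower than in the mean (4327 higher) and 4005 lower than in Pfeiffer (4852 higher). They gave 4115 higher than in KARPAS-422 (4698 lower). Fewer genes were tested in these settings. A 2-fold minimum left 1176 higher and 591 lower with CPI-169, 340 and 492 with GSK343, 90 and 43 in both, 2205 differing between lines, 1991 and 2476 in RL against the mean, 2590 and 2680 against KARPAS-422, 2813 and 4142 against Pfeiffer, and 18 interferon-stimulated genes higher with GSK343 and 13 higher in RL than in Pfeiffer. With Pfeiffer fitted alone, 0 genes were higher, 0 lower and 0 interferon-stimulated genes higher (4634 genes at an unadjusted p under 0.05). The DMSO libraries alone gave 7 interferon-stimulated genes higher in RL than in KARPAS-422. Leaving out each library in turn gave 1207 to 4458 genes higher and 1796 to 4223 lower with GSK343, 590 to 2027 higher and 748 to 1653 lower in both lines, and 19 to 58 interferon-stimulated genes higher with GSK343, 4 to 7 higher in RL than in KARPAS-422 and 14 to 33 higher in RL than in Pfeiffer. CDKN1A, at -0.20 with GSK343, reversed to 1.01 without GSK343 replicate 2 and was -1.40 without replicate 1; the cause was not tested. Of the fits of named genes, 2380 kept direction and side of the threshold under the planned settings, 114 lost the call and 39 gained it, and with a library left out 2973 kept them, 58 lost the call and 40 gained it. Of those of lists, 1342 kept them, 46 lost the call, most of them with an estimated correlation, and 36 gained it, and with a library left out 1548, 7 and 29 did. Median scaling gave 56 interferon-stimulated genes higher with CPI-169 and 32 with GSK343. Absolute depth is unknown, which limits statements on low genes. Deviations of same-numbered libraries from their group means correlated at -0.152, -0.252 and 0.156 in KARPAS-422 and 0.14 in Pfeiffer. With so few libraries per group these values cannot decide whether the replicate numbers pair the samples. With the replicate block, 1502 genes were higher and 2029 lower with GSK343, and 698 and 720 in both lines. The cause of the moves other than by fewer genes, libraries or a stricter threshold was not tested.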

Other observations

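The metallothionein, immediate early and amino acid response lists and the test on histone genes were chosen after the results were seen, while the zinc-finger tests were set before theirs, on a family picked because zinc-finger genes stood among the largest falls in the same data. Metallothionein genes, which bind metal ions, rose with CPI-169 in KARPAS-422, in 5 of 5 members tested (also adjusted over the list alone), with a median log2 fold change of 2.49 (camera adjusted p = 5.67e-05; adjusted p = 0.00915 with an estimated correlation), and 1 of 5 rose with GSK343 in Pfeiffer (camera adjusted p = 0.251). Immediate early genes of the ERK and SRF pathways had 11 of 15 members lower and 2 higher with CPI-169 (also adjusted over the list alone), with a median of -1.35 (camera adjusted p = 4.62e-05; adjusted p = 0.00731 with an estimated correlation). FOS went from 11.9 ± 0.829 to 1.96 ± 0.174 FPKM and EGR1 from 110 ± 12 to 18.3 ± 1.56 (SD, n = 3 each). With GSK343 that list had 2 members higher and 1 lower (camera adjusted p = 0.247). Amino acid response genes had 10 of 24 members lower and 1 higher with CPI-169 (camera adjusted p = 0.0156; adjusted p = 0.562 with an estimated correlation), and 2 lower and 0 higher with GSK343 (camera adjusted p = 0.13). That pooled count joins libraries that moved apart: the list median was -0.895 in GSK343 replicate 1, where all 24 members lay below both DMSO libraries, and 0.22 in replicate 2, where 16 lay above and 6 below. These lists were picked on the same data, so the values describe them and are no independent evidence.

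Several genes outside the named set differed between the 2 GSK343 libraries and were singled out after their values were seen. LGALS9 was 13.8 FPKM in replicate 1 and 0.705 in replicate 2, against 0.778 and 0.634 with DMSO, and FCER2 was 8.004 and 0.204, against 0.321 and 0.579. CYP1A1 was 33.4 and 4.30, against 4.24 and 4.45. ASS1 was 5.54 and 28.0, against 5.38 and 6.73, and PSAT1 was 23.4 and 103, against 72.9 and 74.2.

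Zinc-finger genes fell with CPI-169 in KARPAS-422. Of 440 protein-coding genes named ZNF, 246 were lower and 65 higher, with a median of -0.35 (camera p = 1.08e-08; p = 0.0209 with an estimated correlation; p = 1.32e-08 over 439 genes without the named one), and the median was -0.38 after quantile normalization and -0.41 after median scaling. A general fall of genes at such levels is argued against by 1320 protein-coding genes matched on mean level, whose median was 0.045; gene length was not matched. With GSK343 in Pfeiffer, 78 were lower and 25 higher, with a median of -0.05 and a camera p of 0.442, and the difference between lines was not tested for this family. A family-wide fall with CPI-169 is a hypothesis, and shared reads between similar zinc-finger genes may add to it and were not tested.

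Pfeiffer libraries held more small structured RNA than the others: RMRP was 297, 214, 495 and 275 FPKM in them and at most 38.9 elsewhere, and RN7SL2 was 3179 and 3152 with DMSO, 4318 in GSK343 replicate 1, 1151 in replicate 2 and 154 to 681 elsewhere. A library preparation that keeps RNA without a poly(A) tail may account for this. The 56 replication-dependent histone genes, whose transcripts lack that tail, were higher in Pfeiffer DMSO libraries than in the mean of KARPAS-422 and RL by a median of 1.431. They were kept for reaching 1 FPKM in 2 libraries. Their medians were 3.16 and 2.72 FPKM in the Pfeiffer DMSO libraries and 0.176 to 0.517 in the DMSO libraries of the other lines. Many could thus have entered through Pfeiffer libraries alone, so the difference is no support for such a preparation. That test was chosen after the RNA levels were seen, and histone transcripts also vary with the cell cycle, so a difference between the lines themselves stays open and untested. Among the KARPAS-422 libraries, CPI-169 replicate 1 had 38.9 FPKM of RMRP against 0.866 and 3.41 in the other CPI-169 libraries. RMRP was 3.17, 1.79 and 1.00 FPKM in the KARPAS-422 DMSO libraries. The median of the histone genes was 1.25, 0.615 and 0.684 FPKM in the CPI-169 libraries and 0.257, 0.296 and 0.176 in the KARPAS-422 DMSO libraries, a rise at low values. RN7SL2 did not move with them, at 642, 671 and 589 FPKM with DMSO and 666, 652 and 681 with CPI-169. A shift of RNA composition with the treatment is therefore not shown.

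A run of 7 mitochondrial-like genes on chromosome 1 (hg19, 564442 to 570302) was listed at 0 in GSK343 replicate 2. Elsewhere, 11 mitochondrial-like genes had a median ratio of that library to the mean of the other Pfeiffer libraries of 1.01, from 0.827 to 1.85. These values came from tests of 2 explanations, set before the values were seen. For a lack of mitochondrial reads in that library, the ratio of 1.01 argues only against a lack of reads at mitochondrial-like genes elsewhere. Mitochondrial reads were not seen directly, since all 13 mitochondrially encoded genes are listed at 0 in every library. The test of a missing estimate listed as 0 only repeated that the genes were at 0 and supports nothing. Both were taken out of the set of weighed explanations after these outcomes were seen, to keep that set small. Leaving out the 7 genes changed the counts with GSK343 from 2254 and 3281 to 2264 and 3287.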
